A study of Mus musculus with 7 samples.

How the data were processed

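RNA from 7 mouse cultures was measured on single-colour Affymetrix whole-transcript arrays, with 300 ng of total RNA per labelling reaction, per the labels' protocols. The deposited values are on the log2 scale, and were summarised per probe set with RMA (a method that corrects background, normalizes between arrays and combines probes) per the submitters' processing notes. The RMA version and the software that ran it are not given in the sources used here. The range of the values, 2.80 to 14.5, was checked against that scale. Scanner files were not used here, so the scale and normalization rest on these notes and on the values, and no probe-level background was known.

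Groups were taken from the sample labels: MEF, MEF 3 days after infection, MEF 10 days after infection, Mock, iOPC (2 clones) and OPC. Per the labels' protocols, fibroblasts were seeded at 30000 cells, infected for 24 h, and given OPC medium with 20 ng/ml PDGF-AA and 10 ng/ml FGF-2 from day 3. The labels do not name the factors in the retroviruses. The series' design text speaks of 6 samples and 7 were used here. The 2 clones were treated as replicates of 1 group. They are separate clones, but the labels do not say whether they came from separate infections.

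Probe sets were paired with gene symbols through the platform annotation. Of 34759 probe sets, 21789 had 1 symbol, 1621 had several and 11349 were unnamed in that table. Of those with 1 symbol, 21698 had a gene identifier in the mouse RefSeq table, and 0 symbols changed. For symbols with several probe sets, the probe set with the highest mean over the 7 arrays was kept, which left 19938. This choice was fixed before the data were examined. The names were then checked against the levels of gene families with known abundance, listed after the first values had been seen. They were not borne out, so no gene is named, the rule fixed for naming genes was not applied, and the kept probe sets are a set of unnamed probe sets. The listed symbols still set which probe sets were kept, which were averaged in the alternative with means per symbol, which so joins probe sets that need not belong to 1 gene, and which entered the list check below and the tests of the names. Control probe sets could not be set apart for the same reason. Identifiers are printed only as the deposited table lists them, and should not be read as genes. The 20 gene lists fixed beforehand, with 409 genes of which 382 had a kept probe set, were run as planned as a further check of the names. The camera test in limma, with a preset correlation of 0.01, called 0 of 60 list and contrast pairs, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.748. In the differences between single arrays, 5 of 120 list medians lay outside the central 95% of 10000 random lists matched on mean level in 20 bins, where chance gives 6. No list is described further.

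The planned test was limma 3.58.1 in R 4.3.3: a group-means model on all 7 arrays, eBayes with a variance trend, Benjamini-Hochberg adjustment, and a call at an adjusted p under 0.05 and an absolute log2 difference of at least 1, 2-sided. Only the clones share a group, so the fit had 1 residual degree of freedom and a prior worth 1.16, and single arrays were assumed to vary like the clones. The clones held identical values at 567 of the kept probe sets (2.84%). The p-values of the planned fit measure the spread between the 2 clones and no more. Where fibroblast arrays were pooled as 1 group, the spread between those arrays was added. Comparisons between single arrays were counted at 2-fold with no test. The position between MEF and OPC was the median of the difference from MEF divided by OPC minus MEF. Its value for an unchanged array was simulated 100 times with the moderated SD of each probe set.

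The procedures were tested on simulated data with 200 of 19938 probe sets changed in iOPC, 50 at each fold. The SD of each probe set was drawn from the prior of the planned fit and capped at 1. For iOPC against MEF the planned fit called 0 of 50 at 2-fold, 4-fold, 16-fold and 64-fold alike, and 0 unchanged ones. Its median estimate at 16-fold was 3.95 on the log2 scale. For iOPC against the 4 fibroblast arrays as 1 group, the fit called 26.0% at 2-fold, 62.0% at 4-fold, 88.0% at 16-fold and 96.0% at 64-fold, with 7 calls among unchanged probe sets. All simulated fibroblast arrays were drawn around MEF, with no differences between conditions. On the real arrays the median moderated SD was 0.215 in the pooled fit and 0.168 in the planned fit. The simulated rates therefore need not hold for the real pooled fit. An array simulated at 0.5 of the way from MEF to OPC was placed at 0.504. That simulation took the MEF and OPC arrays as free of error, so it checks the arithmetic of the position and not its bias.

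Alternatives fixed before the data were examined were eBayes without the trend and with a robust prior, a filter at the table median of 7.37, the mean of probe sets per symbol, quantile normalization, median centring, pooled fibroblast groups, limma's treat, untested counts at 2-fold in both clones, other fold thresholds, Mock as the start point and each clone left out. Those added after the data had been seen were all probe sets of the table, probe sets with differing clone values, the counts in both clones as results of their own with their alternatives, the classes between fibroblasts and OPC, infected against uninfected fibroblasts, and single arrays left out of the pooled fits. The comparison of the clones with the 2 infected fibroblast arrays was also added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.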

Results

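Gene expression was measured on 7 mouse arrays, each hybridised with RNA from 1 sample, in a study that set out to turn fibroblasts directly into oligodendrocyte progenitors (OPCs), the dividing cells of the brain and spinal cord that give rise to myelinating oligodendrocytes. Embryonic fibroblasts (MEF) were the starting cells. Fibroblasts collected 3 and 10 days after retroviral infection gave 1 array each, and uninfected fibroblasts kept for 10 days in OPC medium (Mock) gave 1. Induced OPCs (iOPCs), isolated mechanically and expanded as stable clones, gave 2 arrays, 1 for each of clones 1 and 2. OPCs gave 1 array. Of the 6 groups, 5 therefore had a single array, so their values had no replicate check, and the difference between the 2 clones was the only spread within a group.

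The values were log2 expression levels, and 34759 probe sets were listed. Array medians ran from 7.23 in iOPC clone 2 to 7.54 in OPC. The OPC array also had the narrowest distribution, with an SD of 2.25 across probe sets against 2.34 to 2.39 on the other 6 arrays. The number of arrays limited the precision.

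The gene names paired with the probe sets were not borne out by the values, and no gene is named here. Ribosomal protein genes are among the most abundant transcripts of any cell, and olfactory receptor genes are largely silent outside olfactory neurons. The 207 probe sets listed under ribosomal protein symbols had a median level of 7.67, and the 1023 listed under olfactory receptor symbols had a median of 7.92. The chance that a probe set of the first kind was brighter than one of the second was 0.461. Non-adjacent probe sets listed with the same symbol were unrelated in their OPC minus MEF difference (r = 0.0082 across 7961 pairs of probe sets). Comparisons of the same probe set between arrays do not rest on the names, and the results that follow describe cell groups and counts of unnamed probe sets. The counts are over 19938 probe sets, 1 for each listed symbol, as fixed before the data were examined.

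The arrays fell into fibroblasts on the one hand and iOPCs with OPCs on the other. Pairs of fibroblast arrays, infected or not, had Pearson correlations across probe sets of 0.971 to 0.986. The 2 iOPC clones correlated at 0.975 with each other. Clone 1 correlated with OPC at 0.968 and clone 2 at 0.954, whereas the clones' correlations with the 4 fibroblast arrays lay between 0.915 and 0.926. OPC and the fibroblast arrays correlated at 0.909 to 0.921. Probe sets are not independent replicates, so these 21 correlations describe whole profiles and carry no p-value.

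**Figure D1:**
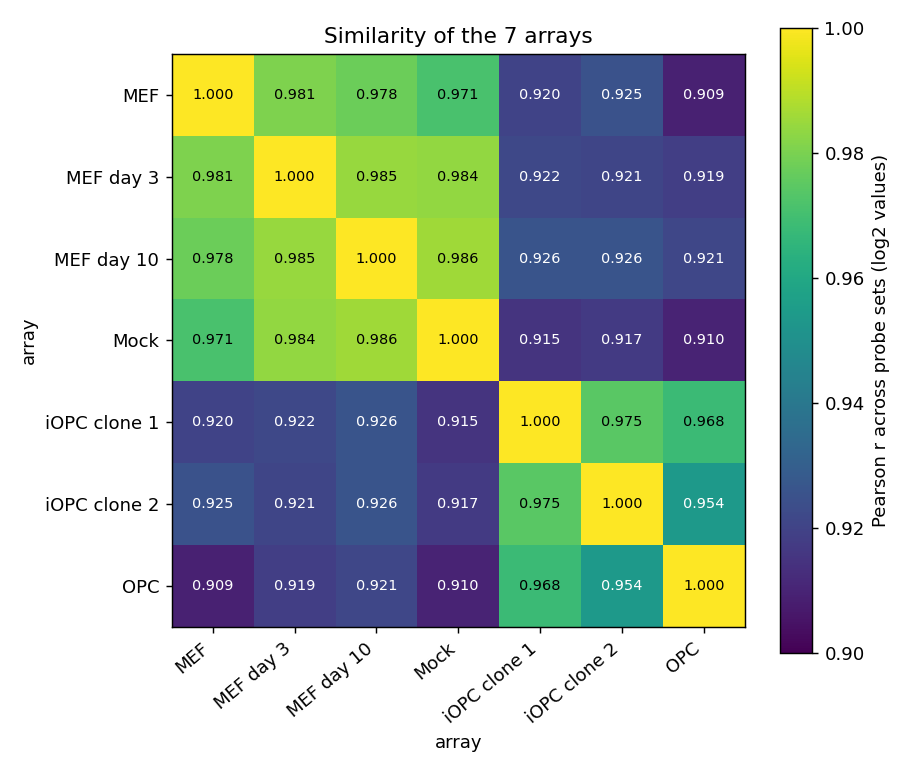
Pearson correlation across 19938 probe sets of log2 values for each pair of the 7 arrays, in colour and as the printed value. The fibroblast arrays form a block at 0.971 or above, and the iOPC clones and OPC form another at 0.954 or above.

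The difference between the end-point cell type and the starting cells set the scale for the conversion. In OPC, 1908 probe sets were at least 2-fold higher than in MEF and 2214 were at least 2-fold lower, together 20.7% of those compared. At 4-fold the counts were 403 higher and 684 lower. The split depended on the scaling between arrays: 46.3% of the differing probe sets were higher in OPC with the values as deposited and 47.0% after quantile normalization, but 26.8% after centring each array on its median. Each array's own median minus the median of the 7 was 0.17 for OPC and -0.08 for MEF, so the centring lowered OPC and raised MEF.

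The next question was how far iOPCs had left the fibroblast state. Both clones were at least 2-fold above MEF at 793 probe sets and at least 2-fold below it at 1189. Against Mock, the fibroblasts kept in the same medium without virus, both clones were at least 2-fold higher at 1021 probe sets and lower at 1230. The balance differed between clones: clone 1 alone was higher than Mock at 1419 probe sets and lower at 1787, and clone 2 alone higher at 1708 and lower at 1648. Both clones were at least 4-fold from Mock at 343 probe sets in the higher direction and at 507 in the lower. The largest shifts were switches between low and high levels. The probe set listed as 10499091 stood at 12.82 ± 0.25 (SD, n = 2) in iOPC and 13.10 in OPC, against 6.42 to 7.16 in the 4 fibroblast arrays. The one listed as 10466402 stood at 5.14 in clone 1, 4.87 in clone 2 and 4.87 in OPC, against 12.72 to 13.15 in the fibroblast arrays. These 2 were chosen after their values were seen, for the size of the smaller clone's difference, but were not the largest in each comparison. Against Mock, 10414137 fell further, from 13.74 to 5.40 in clone 1 and 5.37 in clone 2. Against MEF, 10425601 rose from 7.74 to 14.06 in clone 1 and 14.07 in clone 2.

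The planned limma test, whose spread came from the 2 clones alone, called 0 probe sets in either direction against MEF or Mock at an adjusted p of 0.05 and a 2-fold change. At an unadjusted p under 0.05 and at least 2-fold, limma counted 735 higher and 1101 lower against MEF, and 943 higher and 1112 lower against Mock. In simulated data the same fit called 0 of 50 probe sets changed by 64-fold. That simulation changed 200 of 19938 probe sets, a smaller share than the 9.94% at which both clones were 2-fold from MEF. How often the fit misses changes in these arrays is thus not known. The empty result therefore excludes nothing. It also hung on small choices: after median centring limma called 229 higher and 423 lower against MEF and 413 and 535 against Mock, and without the 567 probe sets whose clone values were identical it called 179 and 334, and 308 and 470. With the 4 fibroblast arrays taken as 1 group, which adds their differences to the spread, limma called 773 probe sets higher and 871 lower in iOPC. With single arrays left out, the counts were 851 higher and 817 lower without MEF, 550 and 662 without Mock, 477 and 599 without the day 3 array, 498 and 663 without the day 10 array, 517 and 471 without clone 1, and 445 and 625 without clone 2. In that fit 10499091 rose by 5.87 ± 0.26 (SE; limma adjusted p = 2.67e-04) and 10466402 fell by 7.94 ± 0.18 (SE; limma adjusted p = 9.62e-05), each in both clones. With only MEF and Mock as 1 group, limma called 101 higher and 162 lower.

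Where both iOPCs and OPCs differed from fibroblasts by 2-fold, they mostly differed in the same direction. Across probe sets, iOPC minus Mock and OPC minus MEF, which share no array, correlated with Pearson r = 0.586 and Spearman rho = 0.328. Clone 1 alone gave r = 0.617 and clone 2 alone 0.510. OPC was at least 2-fold from MEF at 4122 probe sets. Of these, 1576 were at least 2-fold apart in both differences, and 1497 of the 1576 had the same direction. MEF and Mock correlated with each other at 0.971, so both differences subtracted similar fibroblast profiles. No cell type besides fibroblasts, iOPCs and OPCs was measured. A shared departure from fibroblasts and a likeness to OPC are therefore not told apart by these values. In a comparison added after the data had been seen, limma set the clones against the 2 infected fibroblast arrays. It called 360 probe sets higher and 448 lower in iOPC. OPC lay on the same side of the uninfected fibroblast arrays at 97.2% of these 808 probe sets, and at least 2-fold to that side at 77.0%. Over all probe sets the share on the same side was 57.4%. That share includes probe sets with small differences, so it is not matched to the called ones. Infected and uninfected fibroblast arrays correlated at 0.978 to 0.986, so the 97.2% can also reflect a shared departure from fibroblasts.

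**Figure D2:**
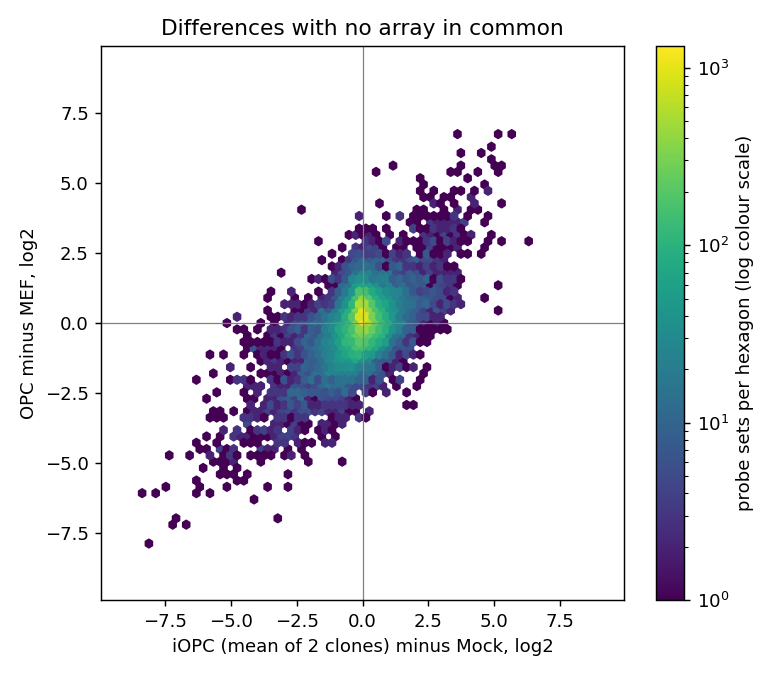
Each probe set's iOPC mean minus Mock (x axis, log2) against its OPC minus MEF (y axis, log2), drawn as hexagons whose colour counts probe sets on a log scale. The cloud runs from lower left to upper right, with Pearson r = 0.586 across 19938 probe sets.

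Each array was then placed on a scale from MEF at 0 to OPC at 1, by the median over the 1087 probe sets at least 4-fold apart between those 2 arrays. The iOPCs lay at 0.884 ± 0.0753 (SD, n = 2), with clone 1 at 0.938 and clone 2 at 0.831. Infected fibroblasts lay at 0.102 on day 3 and 0.136 on day 10. Mock lay at 0.123. Placed directly on a scale from Mock to OPC, the day 10 array lay at 0.0945. These are single arrays, so whether day 10 and Mock differed was not tested. All positions share the MEF array, and an unchanged array simulated with the clones' spread lay at 0.0338. The positions depended on which probe sets were used. Over those at least 2-fold apart, iOPC lay at 0.611, day 3 at 0.211, day 10 at 0.222 and Mock at 0.200. An unchanged array was simulated only for the 4-fold set, so its position over the 2-fold set is not known.

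**Figure D3:**
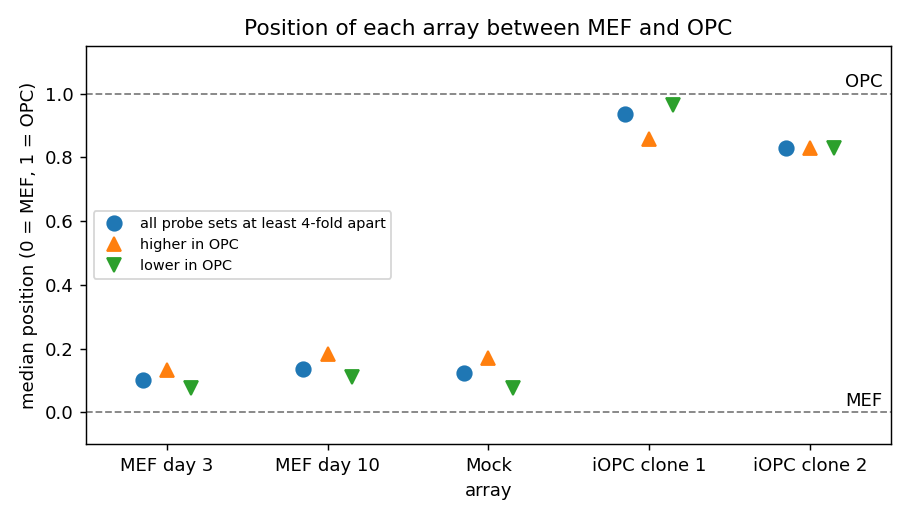
Median position of each array between MEF (0) and OPC (1), over all 1087 probe sets at least 4-fold apart (circles) and over those higher (upward triangles) or lower (downward triangles) in OPC. The clones lie at 0.831 and 0.938, and the infected and Mock fibroblasts at 0.102 to 0.136.

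The distance that the clones had covered towards OPC was then classed for each probe set. With 1 OPC array, the share that another OPC array would reach is not known. At 229 probe sets OPC was at least 4-fold above both MEF and Mock, and at 488 it was at least 4-fold below both. A probe set was counted as at OPC level where the array had covered over 0.75 of the distance from the mean of MEF and Mock to OPC, and at fibroblast level under 0.25. Of the probe sets higher in OPC, 65.5% were at OPC level in clone 1 and 62.4% in clone 2. Of those lower in OPC, 73.2% were at OPC level in clone 1 and 58.2% in clone 2. These shares depended on the fold required: over probe sets at least 2-fold apart, the mean of the 2 clones was 38.7% of those higher and 48.5% of those lower in OPC. At 4-fold, both clones were at OPC level at 53.3% of the 229 probe sets higher in OPC and at 53.9% of the 488 lower. Both clones were at fibroblast level at 22 of the 229 probe sets higher in OPC (9.61%) and at 12 of the 488 lower in OPC (2.46%). On day 10 after infection, 86.9% of the first group and 88.5% of the second were still at fibroblast level, and 1 probe set in all was at OPC level. Probe sets at which Mock lay within 4-fold of OPC had been left out. The day 10 array correlated with Mock at 0.986, so this choice may have raised its share at fibroblast level. These classes were defined after the data had been seen.

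**Figure D4:**
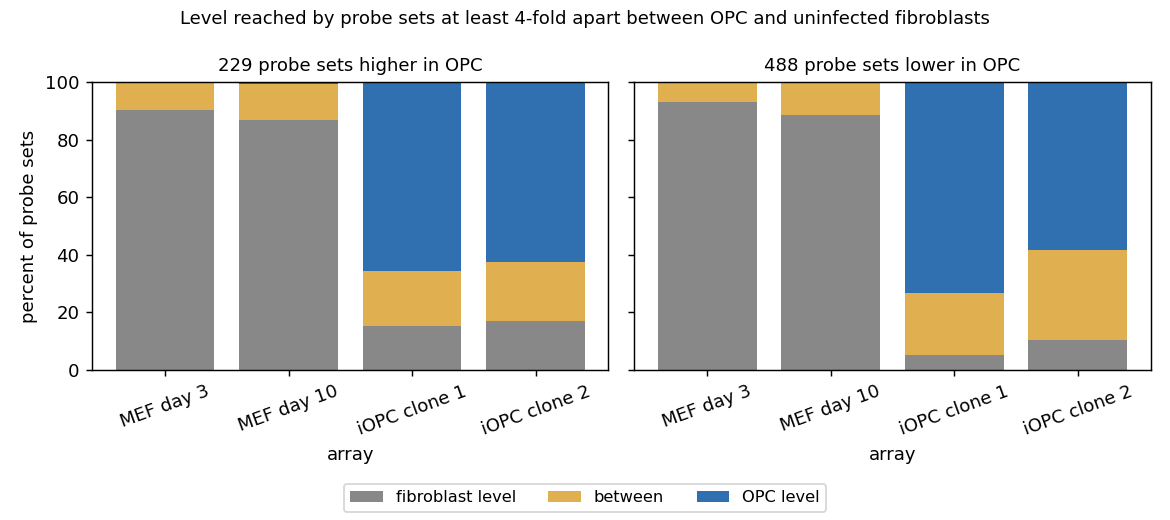
Percent of probe sets at fibroblast level, between, or at OPC level in each infected fibroblast array and iOPC clone, for 229 probe sets higher and 488 lower in OPC. In the clones 58.2% to 73.2% reached OPC level, and in the infected fibroblast arrays 86.9% to 93.0% were at fibroblast level.

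The induced progenitors and OPCs were then compared directly. Both clones were at least 2-fold above OPC at 454 probe sets and at least 2-fold below it at 511, together 4.84% of those compared, against 9.94% for MEF and 11.3% for Mock. For both clones together the counts at 4-fold were 34 and 48. The gap was narrower for clone 2 alone, which was at least 2-fold from OPC at 13.5% of probe sets, from MEF at 14.7% and from Mock at 16.8%. For clone 1 alone these shares were 8.69%, 15.3% and 16.1%. Of the probe sets at which both clones differed from OPC by 2-fold, 47.0% were higher in iOPC as deposited and 44.2% after quantile normalization, but 76.5% after median centring (976 higher and 299 lower), so the balance of the 2 directions depended on the scaling. It also depended on the clone: clone 1 alone was higher than OPC at 816 probe sets and lower at 916, and clone 2 alone higher at 1402 and lower at 1282. The planned limma test called 0 probe sets in either direction, with 463 higher and 514 lower at an unadjusted p under 0.05 and at least 2-fold. With the 4 fibroblast arrays as 1 group to set the spread, limma called 38 higher and 64 lower, and with MEF and Mock as 1 group it called 0 and 0. Those calls did not hold when single arrays were left out: 0 higher and 1 lower were left without MEF, 0 and 0 without the day 3 or the day 10 array, 1 and 4 without Mock, 21 and 20 without clone 1, and 1 and 9 without clone 2.

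The clones differed from each other at 1159 probe sets by at least 2-fold, 409 higher and 750 lower in clone 1. After median centring the counts were 313 and 973. As deposited, the 1159 are 5.81% of probe sets, a smaller share than the 8.69% at which clone 1 and the 13.5% at which clone 2 differed from OPC. Each of these shares compares 2 single arrays.

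The fibroblast arrays were compared with MEF and with each other. Days in culture changed along with infection and medium, and each condition had 1 array, so these counts do not separate culture time, infection and medium. On day 3, 282 probe sets were at least 2-fold above MEF and 541 below, and after median centring 191 and 791. On day 10 the counts as deposited were 457 and 609. Mock, without virus, differed from MEF at more probe sets than either, with 637 higher and 863 lower. At 4-fold the higher direction held more probe sets on day 10 (90 against 44) and in Mock (136 against 80), and the counts on day 3 were 24 and 25. The day 10 cells had been in OPC medium from day 3 and Mock for 10 days. These 2 arrays differed at 241 probe sets in the higher direction and 325 in the lower, or 2.84% of probe sets. An added limma comparison of the 2 infected with the 2 uninfected fibroblast arrays called 0 probe sets, with 67 at an unadjusted p under 0.05 and at least 2-fold. Its smallest limma adjusted p, 0.0504, belonged to the probe set listed as 10506433. That probe set stood at 12.05 on day 3 and 12.75 on day 10, against 6.15 in MEF, 6.16 in Mock, 6.18 and 6.10 in the clones and 6.53 in OPC.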

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

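The use of each test in this part was chosen after the results it weighs had been seen. The list medians and the counts after quantile normalization had themselves been planned. At 6 probe sets one clone lay at least 2-fold above both MEF and Mock while the other lay at least 2-fold below both. The clones thus moved in opposite directions there, with 1 array per clone, and this difference was not tested.

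The clones differed by at least 2-fold at 1159 probe sets. Scaling between the 2 arrays does not account for this, since 1116 probe sets differed after quantile normalization. Leftover fibroblasts in clone 2 are argued against by the 23 probe sets that were high in all 4 fibroblast arrays and low in OPC: clone 2 exceeded OPC there by 0.733% of the fibroblast level at the upper quartile and by -0.0466% at the median. A candidate explanation that stays open is that clone 2 had gone less far towards the OPC state, since clone 1 lay on the OPC side at 73.4% of the 507 differing probe sets that also separated OPC from fibroblasts by 2-fold. Over all 1159 differing probe sets that share was 66.2%, so the lean was not confined to the 507. The other 652 differing probe sets did not separate OPC from fibroblasts by 2-fold, and with 1 array per clone, culture and clone cannot be told apart.

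The listed gene names did not match the levels. Unusual cells with correct names are argued against by the correlation of 0.0082 in OPC minus MEF between non-adjacent probe sets listed with 1 symbol. Values that stand beside the wrong gene names would leave gene lists within the range of random lists, and of the 120 list medians in differences between single arrays 5 lay outside the central 95% of random lists, where chance gives 6. A shuffle of single rows is argued against by the correlation of 0.1832 in mean level between adjacent rows, against 0.00464 after shuffling, so runs of neighbouring values may have kept their order. Which of the identifiers, the values and the annotation is out of place stays open.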

How the results depend on the processing

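The planned test of iOPC against MEF, Mock and OPC called 0 probe sets and did so in all 6 counts without the variance trend, with the robust prior, with the filter on dim probe sets, with means per symbol, with all probe sets of the table (added after the data were seen), with treat and after quantile normalization. With median centring it called 229 higher and 423 lower against MEF and 413 and 535 against Mock. With MEF and Mock as 1 group the counts were 101 and 162, and with 4 fibroblast arrays as 1 group 773 and 871, and 38 and 64 against OPC. Over probe sets with differing clone values (added) they were 179 and 334 against MEF and 308 and 470 against Mock. Against OPC, limma called 0 with median centring, with MEF and Mock as 1 group and over probe sets with differing clone values. With no test, both clones were 2-fold apart at 793 and 1189 (MEF), 1021 and 1230 (Mock), and 454 and 511 (OPC). Leaving out a clone gave untested 2-fold counts of 1166 to 1322 higher and 1610 to 1876 lower against MEF, 1419 to 1708 and 1648 to 1787 against Mock, and 816 to 1402 and 916 to 1282 against OPC. The cause of the calls after median centring was not tested. 

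The untested counts for both clones, with alternatives added after the data were seen, went to 1409 and 2016 (MEF), 1790 and 2088 (Mock), and 819 and 826 (OPC) over all probe sets, because more were counted. At 3-fold they were 377 and 595, 507 and 715, and 101 and 127. The counts for single arrays at 3-fold were 705 higher and 1061 lower for OPC against MEF, 68 and 115 for day 3, 161 and 138 for day 10, 229 and 236 for Mock, 63 and 89 for day 10 against Mock, and 133 and 224 for clone 1 against clone 2. Median centring gave 1167 higher for OPC against MEF. The filter left 357 lower on day 3 and 210 lower for day 10 against Mock, because fewer were counted.

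Over probe sets 2-fold apart, positions were 0.611 for iOPC, 0.667 for clone 1, 0.554 for clone 2, 0.211 on day 3, 0.222 on day 10 and 0.200 for Mock. Over those 8-fold apart they were 0.986 for iOPC and 0.967 for clone 2. No unchanged array was simulated for the 2-fold or 8-fold sets. With Mock as the start clone 2 lay at 0.911 and day 10 at 0.0945. Leaving out a clone gave 0.831 to 0.938 for iOPC. The correlation of iOPC minus Mock with OPC minus MEF was 0.668 with MEF and Mock exchanged, and 0.510 to 0.617 with a clone left out. The mean share of probe sets at OPC level in the clones was 38.7% of those higher and 48.5% of those lower in OPC at 2-fold, and 75% and 81.8% at 8-fold. It was 61.0% of those higher after quantile normalization and 61.3% over all probe sets. The lists outside the range of random lists numbered 8 after quantile normalization. Of 240 alternatives computed, 157 stayed within the limits set for a change. Those include pairs of 0 calls from the planned test and from the list test, which show no stability. Most of the alternatives were counts in 1 direction, which cannot turn. The balance of the 2 directions turned with median centring for both clones together, from 454 higher and 511 lower to 976 and 299 against OPC, and from 1021 and 1230 to 1119 and 1114 against Mock. Against OPC it also turned with the filter on dim probe sets, to 421 and 413, and with clone 1 left out, to 1402 and 1282. Against Mock it turned with clone 1 left out, to 1708 and 1648. For day 10 against MEF it turned from 457 and 609 at 2-fold to 161 and 138 at 3-fold. The cause of these shifts was otherwise not tested. Signal over background was not known, so no level was called absent.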

Other observations

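Both comparisons in this part were chosen after the values had been seen. The probe set listed as 10506433 was the only one of 19938 at least 16-fold higher in both infected fibroblast arrays than in each of the other 5 arrays. Its gap of 5.53 on the log2 scale was wider than the widest gap of any of the other pairs among the 21 pairs of arrays, 4.56. A transcript brought in by the retrovirus might give such a pattern, but its gene is unknown here and the limma adjusted p was 0.0504. Mock minus MEF was 0.003 (log2) there, and the clone mean minus the mean of the uninfected fibroblasts was -0.0139 (log2). The infected arrays lay 6.25 above the uninfected ones on average. The probe set was picked for being low in Mock and in the clones, and that selection let Mock lie at most 1.90 above MEF. A level near the infected one was thus excluded beforehand in Mock and in the clones. These values therefore test neither the medium nor a viral transcript held by the clones, and say nothing about other probe sets. A viral transcript lost or silenced in the clones, and the medium together with infection, were not tested.

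Other probe sets set pairs of arrays apart. Both clones were at least 4-fold above each of the other 5 arrays, OPC included, at 11 probe sets, and at least 4-fold below each at 8. Clone 1 and OPC together were at least 4-fold above the rest at 7 probe sets and below at 19. For clone 2 and OPC these counts were 6 and 3. The day 10 and Mock arrays, both kept in OPC medium, were at least 4-fold above the rest at 7 probe sets and below at 0. For MEF and the day 3 array the counts were 4 above and 7 below, and for MEF and the day 10 array 3 and 0.

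As deposited, the difference between iOPC and OPC varied with level, and the OPC array had the narrowest distribution. Among the dimmest 25% of probe sets the median of iOPC minus OPC was -0.08 (log2), and among the brightest 25% it was 0.19. After quantile normalization the medians were 0.02 and 0.03, so the variation with level depended on the scaling between arrays. Both clones then differed from OPC by 2-fold at 1005 probe sets, against 965 as deposited.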
